A study of Rattus norvegicus with 8 samples.

How the data were processed

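The series measured messenger RNA in thoracic spinal cord of adult male Long Evans rats of about 175 days and 400 g, on 8 Affymetrix Rat Gene 2.0 ST arrays. Per the labels, 4 arrays came from rats with a thoracic spinal cord injury (SCI) and 4 from rats with a laminectomy alone (sham). Chow held 17% fat, 54% carbohydrate and 29% protein at 3.0 kcal/g. After 4 weeks of recovery all rats received a high-fat diet with 40% fat, 46% carbohydrate and 15% protein at 4.54 kcal/g. The labels give a total of 8 weeks, which can be read as the length of the study or of the diet. The diet was common to both groups, so no comparison here concerns it. The cord was taken fresh after decapitation. One label gives the piece as thoracic segments 10 to 11 and another as 11 to 12, and the level of the lesion is not given in the sources used here, so its distance from the sampled piece is unknown. The design text speaks of 10 rats, of which 8 arrays are analysed here. The labels describe each array as a separate sample of its group, but do not tie it to a numbered animal. If any arrays shared an animal, the p-values would measure only a technical spread. Replicates were numbered 1 to 4 within a group in the order of the sample list, and the numbers pair no samples.

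Per the labels' protocols, RNA was isolated with TRIzol and a column kit, checked for integrity, and labelled with biotin for hybridisation. Per the submitters' processing notes, the deposited log2 values were made with Affymetrix Expression Console and RMA (robust multi-array average), which corrects background, brings arrays to a common distribution and summarises the probes of each probe set. No version is named for either tool. The settings of these steps, the probe library and the genome build are not given in the sources used here, so no coordinates are printed. The log base was taken from RMA and from the range of the values. The array medians over all probe sets lay between 3.73 and 3.81 and their SDs between 2.04 and 2.11, so the distributions were close but not identical. A log2 difference of 1 is a doubling of signal, and RMA tends to compress the differences of dim probe sets. No detection calls were used, so a dim gene cannot be called absent. The number of arrays, 4 in each group, limits the precision of every value. RNA was taken from whole tissue, so a difference in signal can come from a different mix of cells as well as from a change within cells.

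The table held 36685 probe sets. The platform annotation gave 1 gene symbol to 18511 of them, several symbols to 575 and none here to 17599. Symbols were matched by gene ID to a RefSeq table of the GRCr8 assembly, which held 18394 of the probe sets, and 0 symbols changed. For the 291 genes with more than 1 probe set, the probe set with the highest mean over all arrays was used, which left 18166 genes. Of 63 other probe sets of called genes, 5 had the opposite sign, 1 of them at an unadjusted limma p under 0.05. Probe sets with several symbols named no gene. Members of families with similar sequences (Lilrb4, Fcrl2, the Clec and RT1 genes) can share probe signal with relatives, and their values are uncertain to that extent.

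SCI and sham were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the log2 values, no covariate) and the Benjamini-Hochberg adjustment, and a gene was called changed at an adjusted p under 0.05. Every adjusted p of a gene is from this limma model. A second count asked also for a change of at least 2-fold. The 49 lists of cell type markers and pathways, with 927 genes of which 817 were tested, were written before the data were examined. They were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists, and again with a correlation estimated from the residuals of these arrays. Directional fry was a further alternative. Camera compares a list with all other genes, and fry does not. Members were counted over all genes tested and also adjusted over the list alone. Differences of list means were tested with an exact two-sided permutation test over the 70 assignments of the 8 arrays, for which 0.029 is the smallest possible p.

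Genes were named by a rule fixed before the data were examined. Symbols of uncharacterised loci, microRNAs, small nucleolar RNAs and olfactory or vomeronasal receptors were left out. The rule took the 12 largest rises and 12 largest falls among called genes whose groups did not overlap. It added the 3 members with the smallest p in each list and any member named as not past the test. It also fixed genes to be named regardless of result, of which 8 were tested (Gfap, Aif1, Cd68, Mbp, Rbfox3, Col1a1, Chat and Slc12a5). Genes outside the rule are said to have been chosen after their values were seen. Members named as not past the test, beyond the 3 with the smallest p, were not set beforehand either. They were picked with their values known, among them Ccr2, Tmem119, P2ry12, Il1b, Il6, Tnf, Gap43, Dhcr7 and Gpr17.

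The model was tested on simulated data made from these arrays' means and spreads over the 18166 genes, for the comparison of SCI with sham. It recovered 28.4% of 67 genes changed by 0.5 on the log2 scale, 85.1% of 67 changed by 1 and 98.5% of 66 changed by 2. Of 148 calls, 7 were false (4.73%). With the cholesterol synthesis list shifted by 0.5, camera called that list and 0 of the 48 others. The simulated values were drawn independently for each gene, so they cannot show false calls of lists that come from correlation between genes. In the real arrays the estimated correlation within a list reached 0.482, in the fibroblast and fibrillar matrix list. The shares of recovered genes and of false calls hold for that number of changed genes, and with more changed genes the adjusted threshold is less strict. The spreads were also shuffled among the genes, so no link between a gene's level and its spread was kept in the simulated data.

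Alternatives fixed beforehand were a second quantile normalization, centring each array on its median, leaving out genes under the median level, an intensity trend with robust variance, array weights, the mean of a gene's probe sets, all probe sets tested, a title number as covariate, an adjusted p under 0.01, a test against a 1.2-fold change, leaving out each replicate, and the other list tests. The title number runs from 4 to 11 and its meaning is not stated. Leaving out the 3 arrays with the least spread values was added after the data were seen. No scan date or batch is given in the sources used here.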

Results

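Messenger RNA was measured on 8 arrays of thoracic spinal cord, 4 from rats with a thoracic spinal cord injury (SCI) and 4 from sham-operated rats, all of which ate a high-fat diet after recovery. Array medians lay between 3.73 and 3.81 on the log2 scale. The correlation between arrays, taken across genes, which are not independent replicates, was 0.972 to 0.981 within a group and 0.963 to 0.973 between groups. The first principal component held 45.6% of the variance and parted the groups, with SCI arrays at 14.2 to 30.25 and sham arrays at -25.27 to -19.62. The second held 11.2% and did not follow the groups. It set SCI 3, sham 1 and sham 2 (-17.18, -12.62 and -12.8) apart from the other arrays (4.53 to 14.79), and these 3 arrays also had the smallest SD of values. No pair of arrays held identical values.

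**Figure D1:**
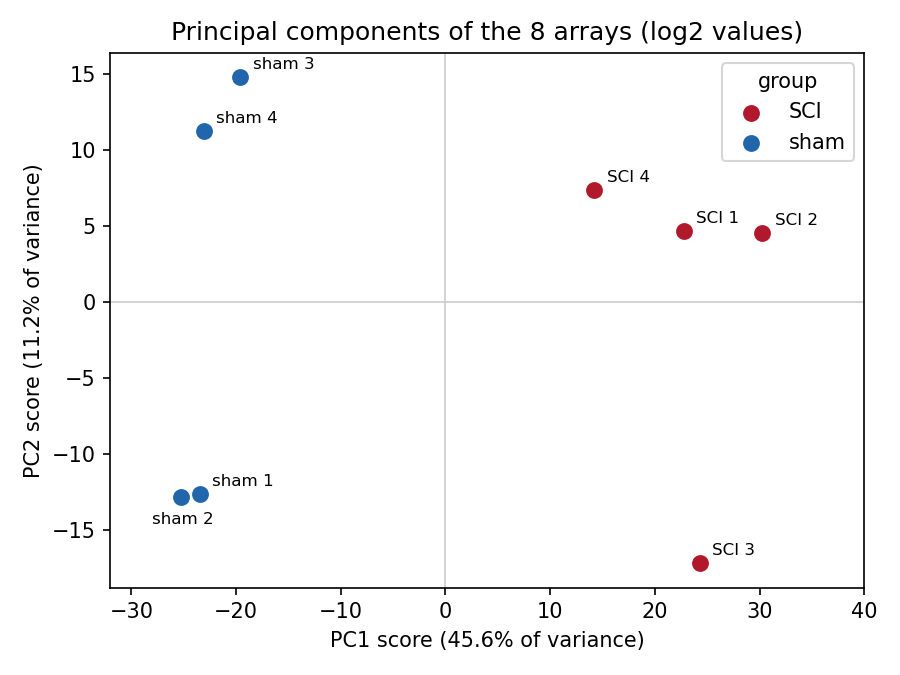
Scores of the 8 arrays on the first 2 principal components of the log2 values of the tested genes, with 1 point per array (red SCI, blue sham). The SCI arrays lie at 14.2 or more on the first component and the sham arrays at -19.62 or less, while SCI 3, sham 1 and sham 2 lie at -12.62 or less on the second.

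The comparison of SCI with sham asks which transcripts differed between injured and sham-operated cord, both on the high-fat diet. In injured cord, 18 of 23 macrophage and pan-myeloid genes and 21 of 23 phagocytic and lipid-laden myeloid genes were higher than in sham, and 17 of 18 cholesterol synthesis, 15 of 20 myelin and 19 of 20 pan-neuronal genes were lower. These 5 lists passed camera at a preset correlation and had adjusted p of 0.084 to 0.086 with an estimated correlation. Gpnmb, a membrane glycoprotein of phagocytes (probe set 17783481), rose from 5.69 ± 0.25 to 10.62 ± 0.16 (log2, SD, n = 4), a 30.5-fold rise with an SE of 0.14 on a log2 change of 4.93 (adjusted p = 3.4e-08). Cd68, a lysosomal glycoprotein of macrophages and microglia (probe set 17657767), rose 18.0-fold (4.17, SE 0.14, adjusted p = 8.8e-08). Fdft1, the squalene synthase (probe set 17703706), fell by 1.71 (SE 0.13, adjusted p = 2.5e-05), from 8.79 ± 0.16 to 7.07 ± 0.21 (log2, SD, n = 4).

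Of 18166 genes, 1290 were higher and 1282 lower in SCI at an adjusted p under 0.05, together 14.2% of those tested. At an unadjusted p under 0.05 the number was 4850. Of all genes tested, 3682 had groups that did not overlap, where chance gives 1 in 35, or 519 genes, at 4 arrays against 4. The rises were larger than the falls. The median change was 0.65 among the higher genes and -0.51 among the lower, and of genes changed at least 2-fold 263 were higher and 27 lower. The median difference over all tested genes was -0.01. With each array centred on its median, 38.8% of called genes were higher, against 50.2% without centring. Lower calls numbered 780 without SCI 2 and 838 without sham 4, and with the title number as covariate 813 genes were higher and 543 lower. Without SCI 3, sham 1 and sham 2, 563 were higher and 284 lower, and the genes changed at least 2-fold numbered 258 higher and 40 lower. Of 143 named genes past the test, 41 lost their call without these 3 arrays and 23 with the covariate. Of the fixed genes, Rbfox3, Slc12a5 and Col1a1 were at adjusted p of 0.10, 0.14 and 0.080 without the 3 arrays, and Rbfox3 and Slc12a5 at 0.058 and 0.054 with the covariate.

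The 12 largest rises were, after Gpnmb and Cd68, in Fcrl2, Lilrb4, Clec7a, Lgals3, Plbd1, Apobec1, Abca1, Siglec1, Ctsk and Mmp12, with log2 changes from 3.91 down to 2.60. Several encode receptors of myeloid cells, among them the beta-glucan receptor Clec7a (3.58, SE 0.17, adjusted p = 1.6e-06) and the sialic acid-binding Siglec1 (2.79, SE 0.15, adjusted p = 3.7e-06). Abca1, which exports cholesterol from cells, rose by 2.85 (SE 0.14, adjusted p = 1.6e-06). Of these 12, Fcrl2, an Fc receptor-like gene, varied most within the injured group, where its SD was 1.41 (change 3.91, SE 0.58, adjusted p = 0.0016). Mmp12, the macrophage metalloelastase, started from a dim sham level of 2.36, below the median of all genes of 4.74. Siglec1 (2.91), Lilrb4 (3.43), Fcrl2 (3.90), Cd68 (4.47), Plbd1 (4.62) and Apobec1 (4.66) also had sham levels below that median. The 12 largest falls were in Fdft1, Idi1, Cyp51, Msmo1, Fdps, Sqle, Slitrk6, Scd, Enpp6, Sc5d, Hsd17b7 and Insig1, from -1.71 to -1.21. Of these, Slitrk6, Scd and Enpp6 are not in the cholesterol synthesis list. Enpp6, a choline phosphodiesterase of newly forming oligodendrocytes, changed by -1.28 (SE 0.27, adjusted p = 0.011).

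**Figure D2:**
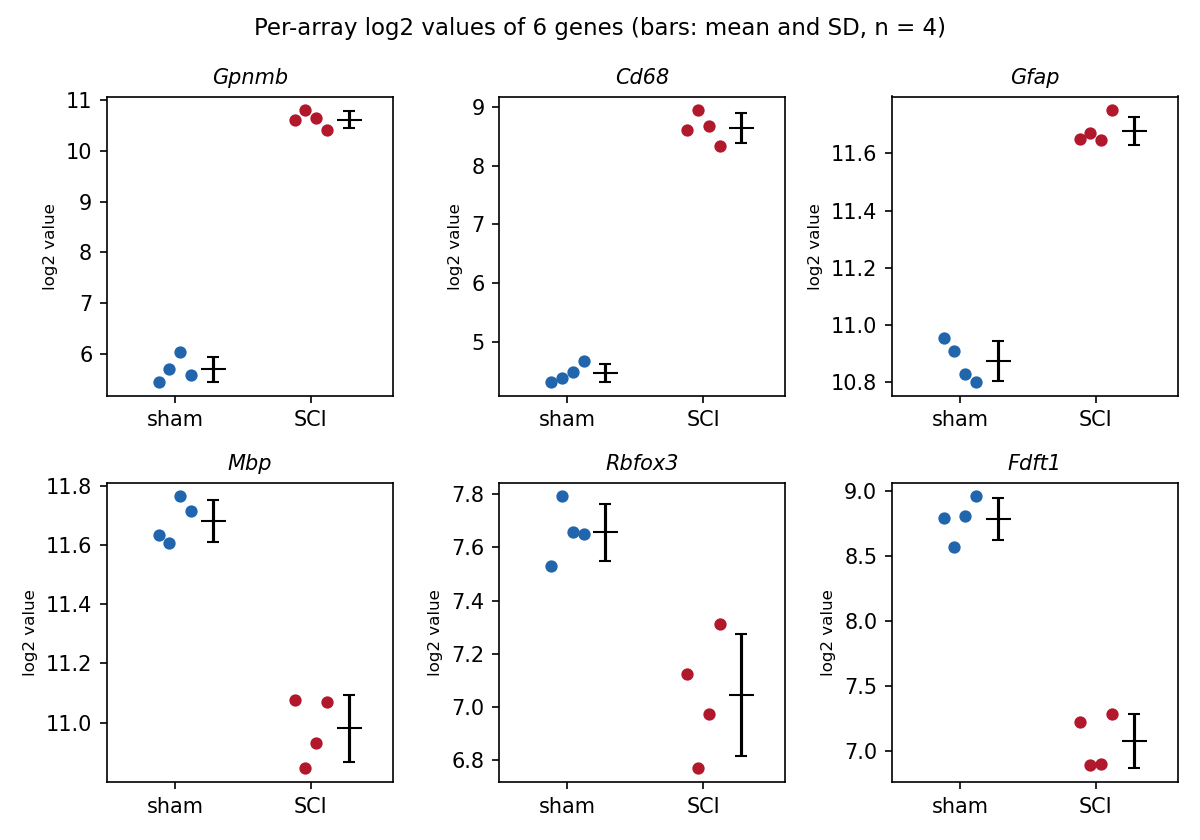
Log2 values of 6 genes on each array (points, red SCI, blue sham), with the group mean and SD (n = 4) at the right of each group and an axis of its own for each gene. In each of the 6 genes every SCI value lies outside the sham range, above it for Gpnmb, Cd68 and Gfap and below it for Mbp, Rbfox3 and Fdft1.

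Myeloid genes formed the largest upward groups. Of 23 macrophage and pan-myeloid genes, 18 were higher and 0 lower, both over all genes and adjusted over the list alone (list median 1.11). Besides Cd68, the adaptor Tyrobp rose by 1.89 (SE 0.14) and the Fc receptor chain Fcer1g by 2.00 (SE 0.15), and the microglial actin-binding gene Aif1 rose by 0.98 (SE 0.13, adjusted p = 8.5e-04). Ccr2, a receptor of infiltrating monocytes, had a difference of 0.11 (SE 0.29). Camera gave an adjusted p of 4.1e-19, and the adjusted p was 0.086 with an estimated correlation. Of 23 phagocytic and lipid-laden myeloid genes, 21 were higher, and 23 adjusted over the list alone, with a median of 1.18. Camera gave 1e-27 for it, and the adjusted p was 0.084 with an estimated correlation. Of 13 homeostatic microglia genes, 7 were higher over all genes, and 8 higher and 1 lower adjusted over the list alone, with a median of 0.45. The phagocytic receptor Trem2 rose by 1.61 (SE 0.16), Csf1r by 0.93 (SE 0.10) and Olfml3 by 1.14 (SE 0.16), while Tmem119 had -0.10 (SE 0.17) and P2ry12 had 0.45 (SE 0.16, adjusted p = 0.085). Camera gave 5.2e-05 for this list, and the adjusted p was 0.086 with an estimated correlation.

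Lysosomal enzymes rose with them. Of 22 lysosome genes 17 were higher, and 18 higher and 1 lower adjusted over the list alone (median 0.87). The hexosaminidase subunit Hexa rose by 1.62 (SE 0.09), and the cathepsins Ctsd and Ctsb by 1.47 (SE 0.09) and 1.48 (SE 0.11). Camera gave 1e-15, and the adjusted p was 0.086 with an estimated correlation. Among 22 genes of oxidative stress and NADPH oxidase, 10 were higher and 2 lower (11 and 2 adjusted over the list alone). The leading members were the phagocyte oxidase subunits Cyba (1.83, SE 0.12), Ncf1 (2.27, SE 0.16) and Cybb (2.04, SE 0.18). The lower members, chosen after their values were seen, were Gclm (-0.46), of glutathione synthesis, and the mitochondrial dismutase Sod2 (-0.35), whose call was lost without any 1 array but sham 2 (0.053 to 0.087). The adjusted p of this list was 4.7e-05, and it was 0.086 with an estimated correlation. Of 17 iron handling genes, 6 were higher and 1 lower, also adjusted over the list alone. Ceruloplasmin, Cp, rose by 2.22 (SE 0.19), the ferritin light chain Ftl1 2.29-fold (log2 SE 0.11) and the haem oxygenase Hmox1 by 1.44 (SE 0.17), while the transferrin receptor Tfrc, chosen after its value was seen, was lower (-0.58), with an adjusted p of 0.063 to 0.078 without SCI 1, SCI 2, sham 3 or sham 4. Camera gave the list an adjusted p of 0.0087, and 0.24 with an estimated correlation. Without SCI 3, sham 1 and sham 2 it was 0.059, and with camera on ranks 0.097.

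The complement, antigen presentation and interferon response lists passed the test upward. Of 14 complement genes 10 were higher and 1 lower (11 and 1 adjusted over the list alone), with rises of 2.12 (SE 0.16) in C1qb, 1.73 (SE 0.14) in C1qa and 1.56 (SE 0.13) in the integrin chain Itgb2. The lower member was C3, at -0.85 (SE 0.14, adjusted p = 0.0027), chosen after its value was seen. For the list as a whole, the adjusted p was 5.1e-10, and 0.092 with an estimated correlation. Of 11 MHC class II genes 5 were higher, also adjusted over the list alone, among them RT1-DMb (1.09, SE 0.14), RT1-Ba (0.87, SE 0.16) and the invariant chain Cd74 (1.12, SE 0.22). The list had 2.6e-04, and an adjusted p of 0.10 with an estimated correlation. Of 15 MHC class I and antigen processing genes 6 were higher, and 8 adjusted over the list alone, led by Psmb8 (0.93, SE 0.10), B2m (0.81, SE 0.10) and Nlrc5 (0.73, SE 0.15). The list had 5.2e-06, and an adjusted p of 0.086 with an estimated correlation. Of 22 interferon response genes 12 were higher, and 19 adjusted over the list alone, led by Ifi27 (1.08, SE 0.11), Mx1 (1.75, SE 0.22) and Irf7 (1.07, SE 0.15). This list had 9.1e-11, and an adjusted p of 0.086 with an estimated correlation.

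Of 30 cytokines and chemokines, 10 were higher and 14 adjusted over the list alone. Cxcl16 rose by 1.28 (SE 0.12), Tgfb1 by 1.05 (SE 0.11) and Ccl3 by 1.32 (SE 0.15). The inflammatory cytokines Il1b, Il6 and Tnf had differences of 0.12, -0.02 and 0.12, with adjusted p of 0.70, 0.93 and 0.68, at levels below the median of all genes. Il1a (0.59, SE 0.18, adjusted p = 0.049) and Ccl2 (0.77, SE 0.16, adjusted p = 0.0081), chosen after their values were seen, were higher, and Il1a lost its call without any 1 array but SCI 3 and sham 4 (0.061 to 0.13). The list had an adjusted p of 2.6e-07, and 0.084 with an estimated correlation. Of 22 markers of T, B, plasma and NK cells, 2 were higher, also adjusted over the list alone. They were Cd8a (1.48, SE 0.12, adjusted p = 5.0e-05) and Cd3g (0.49, SE 0.11, adjusted p = 0.015), and Jchain had 0.32 (SE 0.12). The call of Cd3g was lost with the covariate (0.065) and without SCI 3, sham 1 and sham 2 (0.078). The list did not pass (adjusted p = 0.10 by camera), but passed without sham 2 (0.027) and without SCI 3, sham 1 and sham 2 (0.020). Of 12 neutrophil genes, 1 was higher, also adjusted over the list alone, the collagenase Mmp8 (1.43, SE 0.20), while Prtn3 and Cxcr2 had -0.37 and 0.33 and the list did not pass (adjusted p = 0.55). Cxcr2 passed without SCI 1 (0.55, adjusted p = 0.048). Of 10 blood cell genes, 1 was higher, also adjusted over the list alone, the platelet chemokine Pf4 (1.40, SE 0.25). The haemoglobin gene Hbb-b1 had -0.56 (SE 0.34), Trim10 had -0.36 (SE 0.15), and the list did not pass (adjusted p = 0.47).

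The list of reactive astrocyte genes passed the test upward, and that of astrocytes in general did not pass. Gfap, the astrocytic intermediate filament, rose 1.75-fold, from 10.87 ± 0.07 to 11.68 ± 0.05 (log2, SD, n = 4; SE 0.09, adjusted p = 2.3e-04). Of 24 reactive astrocyte genes 13 were higher, and 14 adjusted over the list alone. The heat shock gene Hspb1 rose by 1.80 (SE 0.14), ceruloplasmin by 2.22 and the protease inhibitor Timp1 by 1.99 (SE 0.19). Camera gave the list an adjusted p of 1.7e-10, and 0.086 with an estimated correlation. Of 13 astrocyte genes, 2 were higher and 1 lower, and 4 and 1 adjusted over the list alone. Gfap and the connexin Gja1 (0.59, SE 0.10) rose, and the glutamate transporter Slc1a2 fell (-0.39, SE 0.11, adjusted p = 0.032). The call of Slc1a2 was lost without any 1 of 6 arrays, all but SCI 4 and sham 1, with adjusted p of 0.064 to 0.088. The astrocyte list did not pass (median 0.13, adjusted p = 0.11). Both lists were accompanied by the rise of the myeloid lists, and Timp1, Cp and Hspb1 are made by other cells as well.

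Myelin genes were lower. Of 20 mature oligodendrocyte and myelin genes 15 fell, and 16 adjusted over the list alone, with a median of -0.58. The hydroxylase Fa2h, which makes myelin lipids, fell by 1.09 (SE 0.11), the link protein Hapln2 by 0.93 (SE 0.11) and the myelin glycoprotein Mog by 0.78 (SE 0.10). Mbp, the myelin basic protein, fell by 0.70 (SE 0.09, adjusted p = 9.0e-04), although another probe set of the gene had -0.07. For the list as a whole, the adjusted p was 2.7e-12, and 0.086 with an estimated correlation. Of 14 oligodendrocyte precursor genes 3 were higher and 2 lower, and 4 and 3 adjusted over the list alone. C1ql1 and Lhfpl3 rose by 0.52 (SE 0.10) and 0.47 (SE 0.11), and the transcription factor Olig1 fell by 0.43 (SE 0.10). These 3 lost their call without SCI 3, sham 1 and sham 2 (0.11, 0.15 and 0.19), and Lhfpl3 also with the covariate (0.051). Pdgfra (0.42) and Sox10 (-0.34), chosen after their values were seen, also passed. Pdgfra lost its call without SCI 2, sham 2 or sham 4 (0.051 to 0.063), and Sox10 without SCI 2, SCI 3, sham 3 or sham 4 (0.051 to 0.060). The precursor list did not pass (adjusted p = 0.24). Of 13 Schwann cell and peripheral myelin genes 3 were higher and 1 lower, and 6 and 1 adjusted over the list alone. Scn7a, Pmp22 and Ncmap rose by 1.25 (SE 0.15), 0.83 (SE 0.11) and 0.91 (SE 0.13), and Plekhb1, chosen after its value was seen, was lower (-0.42). This list had an adjusted p of 3.8e-04, and 0.086 with an estimated correlation.

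Genes that neurons share were lower in all but 1 of the genes tested. Of 20 pan-neuronal genes 19 fell, also adjusted over the list alone, with a median of -0.52. The intermediate filament Ina fell by 0.77 (SE 0.11), the neurofilament Nefm by 0.62 (SE 0.10), the synaptic vesicle gene Syp by 0.58 (SE 0.09) and the neuronal splicing factor Rbfox3 by 0.61 (SE 0.12, adjusted p = 0.0083). Gap43, a growth cone gene, had -0.03 (SE 0.09). The list had an adjusted p of 2.9e-13, and 0.086 with an estimated correlation. Of 14 immediate early genes, which respond within minutes to activity, stress and handling, 6 were higher in the same samples, and 7 higher and 1 lower adjusted over the list alone. Fos, Egr1 and Junb rose by 0.98 (SE 0.10), 0.81 (SE 0.13) and 0.53 (SE 0.09). This list had an adjusted p of 2.2e-04, and 0.11 with an estimated correlation.

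Among neuron classes, the inhibitory list passed with 5 lower genes and 0 higher. Of 12, 5 fell, and 7 adjusted over the list alone, led by the glycine transporter Slc6a5 (-0.67, SE 0.11), the GABA-synthesising Gad1 (-0.58, SE 0.10) and the vesicular transporter Slc32a1 (-0.64, SE 0.13). Without SCI 3, sham 1 and sham 2 Gad1 and Slc32a1 were at 0.059 and 0.096, and with the covariate Slc32a1 was at 0.064. Camera gave the list an adjusted p of 2.7e-04, and 0.092 with an estimated correlation. Of 14 excitatory markers 2 were higher and 2 lower (3 and 2 adjusted over the list alone). The vesicular glutamate transporter Slc17a6 fell by 1.04 (SE 0.14) and Cbln2 by 0.71 (SE 0.15), while the transcription factor Maf, which macrophages express too, rose by 1.32 (SE 0.13), and Reln, chosen after its value was seen, was higher (0.39), but not without SCI 1, SCI 2, SCI 4, sham 1 or sham 2 (adjusted p of 0.061 to 0.076). This list did not pass (adjusted p = 0.83). Of 9 motor and cholinergic neuron genes, 1 fell and 2 adjusted over the list alone. The nuclear receptor Esrrg fell by 0.67 (SE 0.11), the choline transporter Slc5a7 had -0.43 (SE 0.13, adjusted p = 0.051, and 0.027 without SCI 1), Slc18a3 had -0.30 (SE 0.11), and Chat, the acetylcholine-synthesising enzyme, had -0.20 (SE 0.12, adjusted p = 0.31). The list passed at 0.021, with an adjusted p of 0.092 with an estimated correlation and of 0.052 without SCI 3. Without SCI 3, sham 1 and sham 2 together it was 0.11.

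Among 5 lists of receptors, channels and neuropeptides, 4 passed with lower genes and the monoamine receptors did not pass. The pan-neuronal list had a median of -0.52 and the macrophage and pan-myeloid list one of 1.11 in these arrays. Of 17 glutamate receptor genes 9 fell, and 11 adjusted over the list alone, among them Grm3 (-0.74, SE 0.12), Grik4 (-0.58, SE 0.10) and Grin1 (-0.59, SE 0.11), which lost their call without SCI 3, sham 1 and sham 2 (0.057, 0.065 and 0.098), Grin1 also with the covariate (0.052). For the list as a whole, the adjusted p was 5.8e-06, and 0.11 with an estimated correlation. Of 14 GABA and glycine receptor and chloride transport genes 10 fell, and 11 adjusted over the list alone. Gabra5 fell by 0.83 (SE 0.10), Glra1 by 0.82 (SE 0.12) and Gabrb2 by 0.89 (SE 0.14), and the chloride exporter Slc12a5 fell by 0.64 (SE 0.14, adjusted p = 0.010). The list had 8.9e-08, and an adjusted p of 0.13 with an estimated correlation. Of 21 voltage-gated ion channel genes 14 fell, and 16 adjusted over the list alone, led by Kcnc2 (-0.83, SE 0.09), Scn1a (-0.91, SE 0.13) and Kcnq3 (-0.63, SE 0.10). The list had 1.4e-10, and an adjusted p of 0.086 with an estimated correlation. Of 21 neuropeptide genes 3 fell, also adjusted over the list alone, Chga (-0.59, SE 0.13), Nmu (-0.39, SE 0.10) and Vip (-0.62, SE 0.18). That list passed narrowly (0.044), and its adjusted p was 0.25 with an estimated correlation. It lost its call under 8 of 19 alternatives, among them without SCI 2 (0.071), without SCI 3 (0.089) and without sham 3 (0.10). The call of Vip was lost without any 1 array but SCI 4 (0.070 to 0.11), and that of Nmu without SCI 1, SCI 2, sham 1 or sham 3 (0.055 to 0.068). Of 19 monoamine receptors 2 were higher and 2 lower, also adjusted over the list alone. The serotonin receptor Htr2b rose by 1.85 (SE 0.15) and Drd1 by 0.68 (SE 0.12), Htr2c fell by 0.78 (SE 0.14), and Htr1b, chosen after its value was seen, was lower (-0.56). The monoamine list did not pass (mean -0.04, adjusted p = 0.44), but passed downward with genes under the median level left out (mean -0.40, adjusted p = 0.043).

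Of 23 genes of axon growth and injury response 6 were higher and 2 lower, and 8 and 3 adjusted over the list alone. Hspb1 rose by 1.80, the stress gene Gadd45a by 1.29 (SE 0.12) and the injury-induced transcription factor Atf3 by 1.16 (SE 0.16), in the samples in which immediate early genes were higher. The lower members, chosen after their values were seen, were the tubulin-binding genes Stmn4 (-0.82) and Stmn2 (-0.42). The list did not pass (adjusted p = 0.17), and its median (-0.02) and mean (0.17) differed in sign. It passed upward with genes under the median level left out (mean 0.27, adjusted p = 0.034). Of 27 axon guidance and growth inhibition genes 4 were higher and 6 lower, and 4 and 7 adjusted over the list alone. Nrp2 and Sema3c rose by 0.69 (SE 0.09) and 0.75 (SE 0.11), and Slit1 fell by 0.72 (SE 0.10). This list did not pass (adjusted p = 0.20). Of 22 chondroitin sulfate proteoglycan and perineuronal matrix genes 2 were higher and 2 lower, and 3 and 2 adjusted over the list alone. Hapln2 and Hapln4 fell by 0.93 and 0.56 (SE 0.10), Chsy1, which polymerises chondroitin, rose by 0.67 (SE 0.13), and Ncan, chosen after its value was seen, was higher (0.46). The list did not pass (adjusted p = 0.95).

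The lists of fibroblast, meningeal and basement membrane genes passed the test upward. Of 24 fibroblast and fibrillar matrix genes 11 were higher, and 16 adjusted over the list alone, with rises of 1.35 (SE 0.12) in Thbs2, 1.08 (SE 0.13) in Bgn, 1.00 (SE 0.13) in Col1a2 and 0.93 (SE 0.17, adjusted p = 0.0044) in Col1a1. The list had an adjusted p of 2.8e-10, and 0.15 with an estimated correlation. Markers of the meninges, the membranes around the cord, moved with it. Of 15, 8 were higher, and 9 adjusted over the list alone, led by Igf2 (1.44, SE 0.15), Aldh1a2 (0.79, SE 0.13) and Igfbp2 (1.01, SE 0.18). The meninges list had 2.0e-06, and an adjusted p of 0.086 with an estimated correlation. Of 14 basement membrane genes 7 were higher, and 8 adjusted over the list alone, led by Col15a1 (0.97, SE 0.13), Lama1 (0.44, SE 0.09) and Nid1 (0.53, SE 0.12). That list had 1.4e-04, and an adjusted p of 0.086 with an estimated correlation. Of 12 pericyte and smooth muscle genes 3 were higher, also adjusted over the list alone, the peptidase Anpep (2.10, SE 0.17), which myeloid cells carry too, Vtn (1.01, SE 0.15) and Myh11 (0.47, SE 0.14, adjusted p = 0.0498), whose call was lost without any 1 array but SCI 4 (0.063 to 0.13). The list did not pass (adjusted p = 0.058), but passed without SCI 4 (0.043), without sham 3 (0.028), with centring (0.041) and with an intensity trend (0.049).

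Of 16 endothelial genes 1 was higher and 1 lower, also adjusted over the list alone, Cdh5 (0.68, SE 0.14) and the lipid transporter Mfsd2a (-0.57, SE 0.14), whose adjusted p was 0.055 without sham 2 and 0.060 without sham 4, and Flt1 had -0.40 (SE 0.13). The list did not pass (adjusted p = 0.35). Of 13 ependymal and cilia genes 2 were higher, also adjusted over the list alone, Dnah11 (0.73, SE 0.11) and Dnali1 (0.31, SE 0.09), and Rsph1 had 0.19. The call of Dnali1 was lost without any 1 array but sham 2 (0.061 to 0.12). This list did not pass (adjusted p = 0.11), but passed without sham 1 (0.038) and without SCI 3, sham 1 and sham 2 (0.036). None of the dorsal root ganglion (12 tested), skeletal muscle (13) and bone and cartilage (11) genes, which stand for tissue next to the cord, passed over all genes or adjusted over the list alone. Isl1, Prdm12 and Trarg1 had 0.22, 0.33 and 0.52, Myl11, Tnnc2 and Eno3 had -0.25, -0.44 and -0.40, and Sp7, Phex and Col9a1 had -0.38, 0.25 and 0.20. Of these 9 genes, 3 passed without some array: Trarg1 without SCI 1 or sham 3 (adjusted p = 0.031 and 0.042), Prdm12 without sham 4 (0.038) and Tnnc2 without SCI 4 (0.018). The adjusted p of these lists were 0.22, 0.76 and 0.92. The Schwann cell and meninges lists also stand for tissue that the dissected piece could carry, and both passed upward. Camera gave them adjusted p of 3.8e-04 and 2.0e-06, and 0.086 for each with an estimated correlation. Whether such tissue was carried over is therefore left open. Of 13 adipocyte genes 2 were higher and 1 lower, also adjusted over the list alone, Cfd (0.90, SE 0.18), Fabp4 (0.67, SE 0.16), which macrophages express too, and Slc7a10 (-0.55, SE 0.13), and the list did not pass (adjusted p = 0.96). The adjusted p of Fabp4 was 0.053 without sham 4, and that of Slc7a10 was 0.055 to 0.058 without SCI 1, SCI 2 or sham 2. Median and mean differed in sign in the skeletal muscle list (0.01 and -0.04), the bone and cartilage list (0.02 and -0.001) and the adipocyte list (-0.05 and 0.03). In the skeletal muscle list the test followed the mean, in the bone and cartilage list the median and in the adipocyte list the mean.

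Cholesterol synthesis was the list with the lowest median, -1.21. Of 18 genes tested 17 fell, and all 18 adjusted over the list alone. Cyp51, the lanosterol demethylase, fell by 1.69 (SE 0.12, adjusted p = 1.6e-05), Sqle, the squalene epoxidase, by 1.41 (SE 0.10, adjusted p = 2.1e-05), and Fdft1 by 1.71. Dhcr7, the last reductase of the pathway, had -0.33 (SE 0.13, adjusted p = 0.13). Camera gave the list an adjusted p of 1.5e-19, and 0.084 with an estimated correlation. Of 19 genes of fatty acid synthesis and elongation 10 fell and 1 rose, and 13 and 2 adjusted over the list alone. The citrate lyase Acly fell by 0.76 (SE 0.09) and the elongase Elovl7 by 0.93 (SE 0.11), while Srebf1, a transcription factor of lipid synthesis, rose by 1.72 (SE 0.12, adjusted p = 1.6e-05). This list had 1.8e-04, and an adjusted p of 0.092 with an estimated correlation. Both lists moved with the myelin list, whose cells make large amounts of sterols and fatty acids.

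Of 19 fatty acid oxidation genes 2 were higher, and 1 adjusted over the list alone, the uncoupling protein Ucp2 (1.01, SE 0.13) and Eci1 (0.37, SE 0.11, adjusted p = 0.042), whose call was lost without any 1 array but sham 2 (0.055 to 0.12), while Ppargc1a had -0.32 (SE 0.12). The list did not pass (adjusted p = 0.13). Of 27 oxidative phosphorylation genes 7 fell, and 10 adjusted over the list alone, with a median of -0.24. In the same arrays the pan-neuronal and myelin lists had medians of -0.52 and -0.58, and the macrophage and pan-myeloid list 1.11. Ndufb9, Ndufb3 and Ndufs1, subunits of the first respiratory complex, fell by 0.43 (SE 0.09), 0.41 (SE 0.10) and 0.45 (SE 0.11). Ndufb3 lost its call without SCI 1, SCI 2, SCI 3, sham 3 or sham 4 (0.051 to 0.063) and Ndufs1 without SCI 1, SCI 2, sham 3 or sham 4 (0.051 to 0.065). With the covariate Ndufb9, Ndufb3 and Ndufs1 were at 0.073, 0.13 and 0.086, and without SCI 3, sham 1 and sham 2 Ndufb9 and Ndufb3 were both at 0.10. The list had 4.0e-07, and an adjusted p of 0.089 with an estimated correlation. Of 20 genes of insulin, leptin and growth factor signalling 4 were higher and 1 lower, and 5 and 2 adjusted over the list alone. Igf1 rose by 1.95 (SE 0.13, adjusted p = 1.6e-05), and Igf2 and Igfbp2 by 1.44 and 1.01. Socs3 (0.77) and the receptor substrate Irs2 (-0.64), chosen after their values were seen, also passed, though Socs3 did not without SCI 2 (adjusted p = 0.056) or sham 4 (0.052). The list had 0.0070, with an adjusted p of 0.22 with an estimated correlation and of 0.063 without SCI 3, sham 1 and sham 2, and 3 of its 4 higher members are also in the meninges or reactive astrocyte lists. Of 23 cell cycle genes 8 were higher, and 9 higher and 1 lower adjusted over the list alone. Top2a, Mki67 and Aurkb rose by 0.92 (SE 0.10), 1.21 (SE 0.16) and 0.55 (SE 0.12), from sham levels below the median of all genes. The list had 5.9e-05, and an adjusted p of 0.086 with an estimated correlation. With genes under the median level left out it did not pass (adjusted p = 0.41). Of 11 housekeeping genes 1 was higher, and 2 adjusted over the list alone. It was Gusb, a lysosomal enzyme (1.22, SE 0.11), while Actb and Polr2a had 0.31 and 0.30, and the list did not pass (adjusted p = 0.35).

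The calls of some named genes did not hold in 2 further comparisons. Both with the title number as covariate (adjusted p of 0.051 to 0.20 for the genes lost) and without SCI 3, sham 1 and sham 2 (0.0502 to 0.29), the calls of Aurkb, Cd3g, Cd74, Cfd, Dnali1, Eci1, Fabp4, Grin1, Lhfpl3, Mfsd2a, Myh11, Ndufb3, Ndufb9, Nid1, Nmu, Rbfox3, Slc12a5, Slc1a2, Slc32a1, Slc7a10 and Vip were lost. With the covariate alone those of Ndufs1 and Nlrc5 were lost too. Without the 3 arrays alone those of Aldh1a2, C1ql1, Cdh5, Chga, Chsy1, Col1a1, Drd1, Esrrg, Gad1, Gja1, Glra1, Grik4, Grm3, Hapln4, Htr2c, Lama1, Nefm, Olig1, Pf4 and Syp were lost. Other alternatives took the calls of Dnali1, Eci1 and Myh11 (centring, and a second quantile normalization), Dnali1 and Nmu (intensity trend) and Ndufb3 (mean of its probe sets). Named genes that gained a call under some alternative fixed beforehand, apart from single arrays left out, were Slc5a7, Actb, Polr2a, Flt1, Ppargc1a and Slc18a3.

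Camera called 19 of the 49 lists higher and 11 lower at the preset correlation. With an estimated correlation it called 0, with the smallest adjusted p at 0.084, and directional fry called 38. Of these, 8 had not passed camera: the T, B, plasma and NK cell, astrocyte, oligodendrocyte precursor, axon growth, axon guidance, pericyte, housekeeping and fatty acid oxidation lists (fry adjusted p of 0.0027 to 0.036). The calls of lists therefore rest on the preset correlation, while the counts of members rest on the test of each gene.

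**Figure D3:**
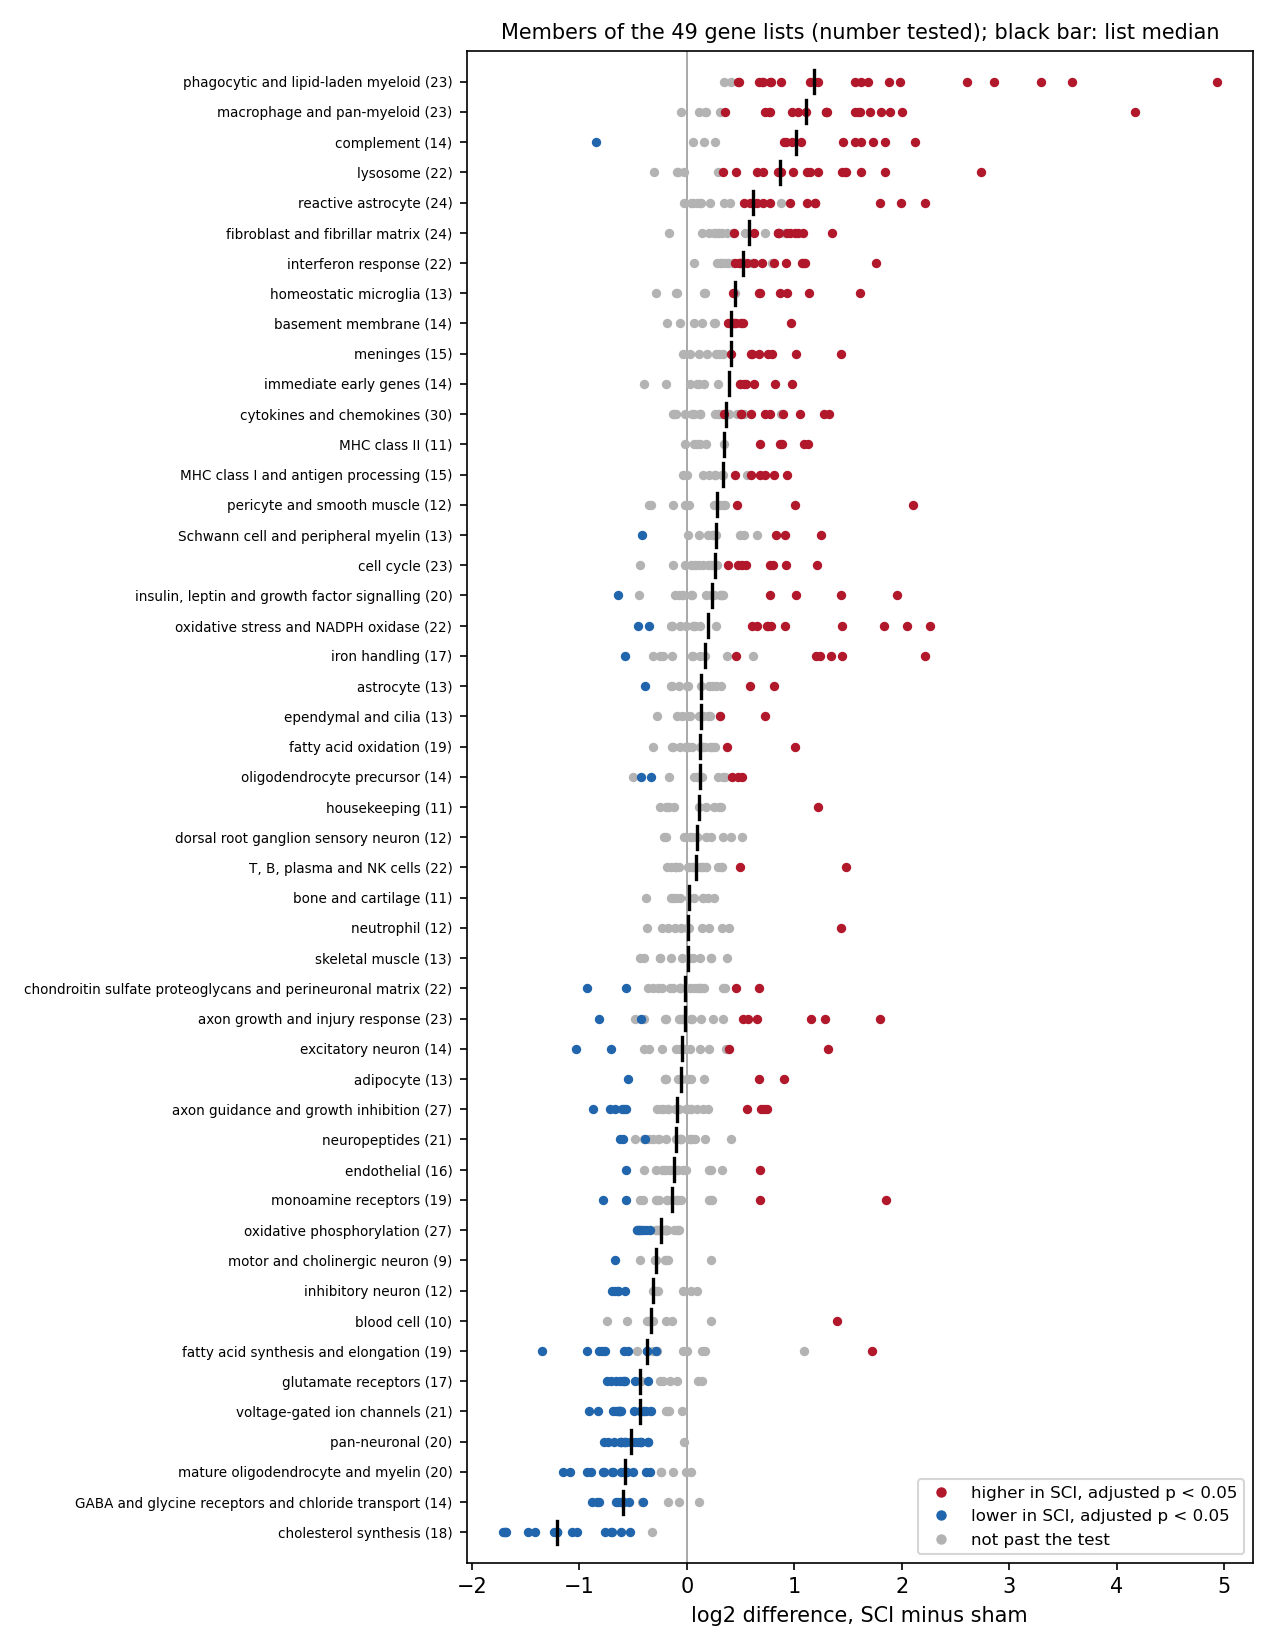
Log2 difference between SCI and sham of each tested member (points) of the 49 lists, in order of the list median (black bar), with red and blue for members higher and lower at an adjusted p under 0.05 and grey for the others. Medians run from -1.21 for cholesterol synthesis to 1.18 for phagocytic and lipid-laden myeloid genes.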

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

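The tests of blood, microglial state, dilution, tissue mix, oligodendrocyte share and sterol sensing were chosen after the results were seen. The counts over splits of the arrays were planned.

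Genes of macrophages and of phagocytosis stood far above sham in injured cord. Blood carried over with the tissue would raise the abundant haemoglobin genes as much, but Hba-a1 and Hbb-b1 together had a mean difference of -0.47, and the macrophage list moved above them by 1.625 (exact permutation p = 0.029, n = 4). More resident microglia in an unchanged state would raise the phagocytic and lipid-laden myeloid list no more than the homeostatic microglia list. The phagocytic list instead moved above the homeostatic one by 1.045 (exact permutation p = 0.029, n = 4). The 2 lists were picked after their medians of 1.18 and 0.45 were seen, so this p adds little to those values. A change of state in resident microglia and an entry of monocytes both remain as hypotheses, and the design holds no test that parts them. The level of the lesion and the amount of scar in the piece may also differ between the groups, and neither was tested.

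Pan-neuronal and myelin genes were both lower. An even dilution of the resident cells by added cells would lower the astrocyte, oligodendrocyte precursor and endothelial lists alike. These lists changed by 0.139, 0.096 and -0.063, and the neuronal and myelin lists fell below them by a difference of -0.594 (exact permutation p = 0.029, n = 4). The lists were picked after their values were seen, so this p adds little to those values. A shift of grey against white matter in the dissected piece would move the myelin and pan-neuronal lists in opposite directions. Instead myelin changed by -0.558 and the pan-neuronal list by -0.515. These are the values of the pattern itself and speak against such a shift only as the whole cause. Dilution together with an increase of astrocytes and precursors could give the same picture, as could fewer neurons and oligodendrocytes or lower expression in each, and these remain open. The piece may also have been taken at another distance from the lesion on each array, which was not tested.

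Genes of cholesterol synthesis fell more than any other list by median. A lower share of mature oligodendrocytes as the whole cause would lower them no more than the myelin genes. The difference between the lists was instead -0.568 (exact permutation p = 0.029, n = 4). The 2 lists were compared after their medians of -1.21 and -0.58 were seen, so this p adds little to those values. A sterol excess could lower synthesis and, where the nuclear receptor LXR senses it, raise LXR targets. The mean of the LXR targets rose by 0.89 (exact permutation p = 0.029, n = 4), with 11 of 14 higher and 2 lower (Scd at -1.35 and Acsl3 at -0.55). This cannot be told apart from the rise of macrophages, since the LXR targets rose by less than the macrophage list (difference -0.269) and 6 of them are in the phagocytic list too. Fewer newly formed oligodendrocytes also remain open, with Enpp6 at -1.28 and Bcas1 at -0.56, but Gpr17 at 0.33 did not pass (adjusted p = 0.066, and 0.036 without sham 1). In these tests 0.029 is the smallest p that 4 arrays against 4 allow.

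Chance as the origin of the gene counts was tested with splits of the arrays. A share of 1 in 35 speaks against chance, but it is the smallest share possible and cannot exclude it. Every split but the real one mixes SCI and sham arrays, so a difference between the groups widens the spread within its groups and lowers its count. Of the 35 splits of the 8 arrays into 4 and 4, 1, the real one, gave as many as 2572 changed genes, and the highest other split gave 0 with limma. At an unadjusted p under 0.05 the real split gave 4850 genes and the others 407 to 1795. For genes changed at least 2-fold the number was also 1 of 35, with 290 in the real split and 0 in the highest other. For the number of shifted lists chance was not excluded, since 3 of 35 splits, the real one included, gave as many as 30 lists, and the highest other split gave 30. The other 2 splits kept SCI 1, SCI 2 and SCI 3 together and so kept part of any group difference. Splits that parted the groups 3 to 1 gave 16 to 30 lists, and those with 2 SCI and 2 sham arrays on each side gave 0 to 4. With a preset correlation camera thus called many lists for groupings that parted the groups 3 to 1, in which limma called 0 genes.

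An array stood apart from the rest of its group in 19 of 428 groups of 4 examined for named genes and list means, against 21.4 that a rate of 1 in 20 gives by chance. Among the genes in sham arrays, Ccl3 was high in sham 2 at 3.48 (others 3.14 to 3.19), Pmp22 was high in sham 2 at 9.98 (9.74 to 9.78), and Cxcl16 was low there at 5.85 (6.12 to 6.17). Slc6a5 was low in sham 1 at 7.89 (8.10 to 8.12) and Vip was high there at 4.41 (3.98 to 4.03). Mki67 and Trarg1 were high in sham 3, at 4.19 (3.93 to 3.96) and 4.06 (3.59 to 3.67). In the SCI arrays, Ifi27 and Igf2 were high in SCI 2 at 10.0 (9.67 to 9.71) and 8.90 (8.35 to 8.40), and Gusb was high in SCI 3 at 5.39 (5.23 to 5.24). In SCI 4, Itgb2 was low at 6.63 (7.05 to 7.09) and Ndufb3 was high at 8.25 (7.98 to 8.02).

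The list means that stood apart in the sham group were those of phagocytic genes in sham 3 (5.83, others 5.67 to 5.70), myelin in sham 2 (9.28, others 9.31 to 9.32), motor neurons in sham 4 (5.37, others 5.48 to 5.49), excitatory neurons in sham 1 (5.11, others 5.14) and monoamine receptors in sham 2 (4.42, others 4.26 to 4.28). In the SCI group they were those of ependymal genes in SCI 4 (3.95, others 4.01 to 4.02) and cell cycle genes in SCI 4 (4.10, others 4.29 to 4.31). By array, the number was 5 in sham 2, 4 in SCI 4, 3 each in sham 1 and sham 3, 2 in SCI 2, 1 each in SCI 3 and sham 4, and 0 in SCI 1.

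Probe sets outside the comparison of genes also differed. Of 17599 probe sets with no gene symbol here, limma over all probe sets called 200 higher and 173 lower in SCI (2.12%), with a largest rise of 3.76. Of 575 with several symbols, 18 were higher and 16 lower (5.91%).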

How the results depend on the processing

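Leaving out the 3 arrays with the least spread values was chosen after seeing the data, and the other settings were planned. No paired analysis was possible because the title numbers differ between the groups and the replicate numbers only name samples. A second quantile normalization, centring, leaving out dim genes, an intensity trend, array weights, the mean of a gene's probe sets, fry and camera on ranks moved no count of genes or lists by over 1.5 times. With 1290 genes higher and 1282 lower in the comparison as reported, testing all probe sets gave 838 lower (54 lower by at least 2-fold), the title number as covariate 813 higher and 543 lower, an adjusted p under 0.01 715 and 471, a test against a 1.2-fold change 471 and 164, and the set without the 3 arrays 563 and 284. A stricter threshold lowers a count by construction. The set without the 3 arrays held SCI 1, SCI 2 and SCI 4 against sham 3 and sham 4, and fewer arrays make the test harder to pass. The genes changed at least 2-fold numbered 258 higher and 40 lower in that set and 250 and 25 with the covariate, against 263 and 27 as reported. How far the smaller set, the larger SE or the larger number of rows accounts for the lower counts was not tested. The title number correlated with group (r = -0.546) and raised the median SE 1.222-fold, and whether it marks a batch was not tested. Of the genes called with it, 1282 of 1356 were among the 2572, and without the 3 arrays 787 of 847. Leaving out 1 array gave 780 (without SCI 2) to 1283 (without SCI 4) lower genes, with 838 without sham 4. An estimated correlation gave 0 lists higher and 0 lower. Of 143 named genes past the test, 11 lost their call without some single array, and 23 with the covariate and 41 without the 3 arrays.

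None of the results that changed sign had passed the test, and the cause was not tested. Centring gave the adipocyte list -0.0188. Leaving out dim genes, which changes the members, gave -0.3157 for adipocyte, 0.0216 for proteoglycan, -0.0124 for ependymal and 0.1549 for blood genes, and the covariate gave 0.0324 for bone. Leaving out 1 array, the means ranged from -0.0725 to 0.0039 for excitatory, -0.0519 to 0.0011 for monoamine, -0.0708 to 0.0015 for proteoglycan, -0.0214 to 0.0246 for bone and -0.3211 to 0.0013 for blood genes. Without the 3 arrays, Sp7 was at 0.0156, and the monoamine, skeletal muscle and bone lists at 0.0099, 0.024 and 0.0151. No detection calls bound the dim genes, so how far signal near background limits them is unknown.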

Other observations

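Except Cd8a, Cd3g, Srebf1 and Fcrl2, the genes in this part were chosen after their values were seen, and no test beyond limma's was run on them.

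Genes of T cell coreceptors and of the CD3 chains had changes of different size, and which cells carried the coreceptors was not tested. Cd8b rose by 2.58 (SE 0.14, adjusted p = 4.2e-06), Cd8a by 1.48, Cd4 by 0.95 (SE 0.12, adjusted p = 5.7e-04), and the CD3 chain Cd3g by 0.49 (SE 0.11, adjusted p = 0.015, but 0.065 with the title number as covariate and 0.078 without SCI 3, sham 1 and sham 2). Cd3e had 0.13 and Cd3d 0.18 and neither passed. The 3 CD3 genes were dim, at 2.31, 2.28 and 2.46 in SCI. The metallothioneins Mt1 and Mt2A, which bind zinc and copper, were higher by 2.10 and 1.65 (adjusted p = 2.5e-04 and 2.8e-04). Hpgds, a prostaglandin D synthase, rose by 2.57, and the thromboxane synthase Tbxas1 by 2.03. The lysosomal channel Mcoln3 rose by 2.43 and the chemokine Cxcl14 by 2.30. Grn, the progranulin gene, rose by 1.84.

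Further lipid genes moved both ways. Pltp, which transfers phospholipids, rose by 1.70, the cholesterol-oxidising Cyp27a1 by 0.95 and Lcat, which esterifies cholesterol, by 0.96. Acss2 and Aacs, which make the acetyl and acetoacetyl units used for lipids, fell by 0.97 and 0.82. Cyp46a1, the cholesterol hydroxylase of neurons, had 0.01 (adjusted p = 0.96). The transcription factors of lipid synthesis moved apart, with Srebf1 at 1.72 and Srebf2 at -0.71 (adjusted p = 0.0050).

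Fcrl2 differed between the arrays of the injured group, with values of 9.41, 6.80, 6.46 and 8.55 on SCI 1 to SCI 4, and so did the interferon-induced Ifitm1, whose SD was 1.23 in SCI and 0.18 in sham.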
